A study of Mus musculus with 10 samples.

How the data were processed

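Gene expression was measured in hearts of male SV129 mice 32 weeks old, either wild type (WT) or lacking the atypical protein kinase C isoform PKCz (KO, the label being PKCz −/−). The mice were littermates, per the labels. They received angiotensin II (AngII) at 432 µg per kg per day for 14 days from osmotic minipumps, or the solvent PBS. The titles and the design text name PBS for the controls while their source label calls them untreated, so the groups are called PBS here. Arrays were assigned to 4 groups from the labels: WT PBS (n = 2), WT AngII (n = 3), KO PBS (n = 3) and KO AngII (n = 2). Single arrays are named by group and title number, as in WT AngII 2.

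Per the labels' protocols, total RNA was extracted with a column kit, and biotinylated cRNA was prepared from 6 µg of it for 1-colour Affymetrix arrays. The deposited values are log2 expression values of 45101 probe sets, made with RMA per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set. Its version and the probe set definitions are not given in the sources used here. Because RMA shares information between arrays, a distorted array can slightly shift the others, and small differences of dim probe sets are compressed. The array medians lay between 6.12 and 6.23 and the values between 3.06 and 14.68 (log2). No read depth applies to arrays; the number of arrays limits the precision.

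The 64 control probe sets were left out, and 45037 were tested. GEO's platform annotation gave 1 gene symbol for 34945 of the 45037 probe sets and several for 932. The remaining 9160 are unnamed here. Symbols were updated by Entrez identifier for 34741 probe sets with the RefSeq gene table of assembly GRCm38.p6, which served only for names and for which genes neighbour each other. Each of 18193 genes was represented by its probe set with the highest mean over all arrays among those with 1 symbol. Other probe sets of a gene can differ from it, and are given for part of the named genes only.

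Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit on 4 group means over all 10 arrays, eBayes with trend), with two-sided moderated tests. P-values were adjusted by Benjamini-Hochberg over all 45037 probe sets within a comparison, and a call means an adjusted p under 0.05. The fit had 6 residual degrees of freedom, and a median of 11.7 after moderation. There were 7 comparisons: AngII against PBS in WT and in KO, the difference between these effects (interaction), KO against WT under PBS and under AngII, and the averages over genotype and over treatment. Values are log2 differences ± SE unless SD is stated. The targeted gene was also tested by an exact permutation of genotype within treatment.

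A total of 36 gene lists (21 pathways, 15 cell types) were tested in each comparison, 252 tests in all, with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Camera compares a list with the other genes. It was repeated with the correlation estimated from the data, and fry tested whether the genes of a list moved on balance in 1 direction. With the estimated correlation 0 lists were called in any comparison, and likewise by fry. List values are the median log2 difference over the measured members. In each called list the median, the mean and camera had the same sign.

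The genes named in every comparison are Prkcz, Mapk7, Map2k5, Gnaq, Sqstm1, Nppa, Nppb, Myh7 and Acta1; Myh6 was chosen too and is given for the AngII effects only, as its brightest probe set lay near the top of the scale. Beyond these the rule took up to 10 called genes with the largest rise and 10 with the largest fall; where fewer than 20 passed, it took every gene that passed and then, as values only, the genes with the smallest unadjusted p up to 20. For a described list it took the 2 to 4 members with the smallest unadjusted p. The groups, comparisons, tests, lists, this rule and the alternative settings were fixed before the data were examined. These settings were equal array medians, repeated quantile normalisation, only probe sets at or above the median level, eBayes without trend or robust, array weights, the title number as a replicate block, only the arrays of the groups compared, the mean of a gene's probe sets, and leaving out each array in turn. Chosen after seeing the data were a block for the spike-in batch described with the data, fits within each batch, and fits without WT AngII 2 combined with that block or with leaving out WT PBS 5. Where an array left out leaves a group with 1 array, the lone array is assumed to vary like the other groups.

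The scripts were tested on simulated arrays of 45037 probe sets with 200 changed. For AngII against PBS in WT, limma recovered 73% of the 2-fold and 97% of the 4-fold changes with 5 false calls. For KO against WT averaged over treatments it recovered 93% and 99% with 6 false calls. A list shifted by 0.50 log2 reached a camera adjusted p of 9.34e-09 in the former comparison and 3.53e-12 in the latter, and 0 other lists were called. The simulated probe sets varied independently, without a batch or an array that stands apart. The absence of other called lists there therefore does not bear on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.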

Results

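The study infused AngII, a peptide hormone that raises blood pressure and enlarges the heart, into mice with and without PKCz, a kinase its title places between the G protein alpha-q and the ERK5 pathway. Transcript levels of the heart were read on 10 arrays, WT PBS 3 and 5, WT AngII 2, 3 and 4, KO PBS 2, 3 and 4, and KO AngII 3 and 4. The labels do not say that the arrays of a group come from separate animals, so the p-values measure only the spread between these samples, which may be technical. Over all probe sets, pairs of arrays correlated with r from 0.9734 to 0.9951.

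The arrays fell into 2 batches by their control transcripts. Polyadenylated bacterial RNAs, added to a sample before labelling, read 6.90 to 7.08 log2 on KO PBS 4, KO AngII 3 and KO AngII 4 and 12.86 to 13.33 on the other 7 arrays (mean over 24 probe sets), a difference of 6.11. The 3' minus 5' signal of beta-actin, a sign of how far labelling reached, was 0.74 to 0.83 on the low arrays and 0.92 to 1.70 on the high arrays. Both KO AngII arrays were low, all WT arrays were high, and KO PBS held 2 high and 1 low. The log2 differences within WT are therefore free of this batch. Their SE and p are not wholly so, as the spread is estimated over all arrays. Most called genes and lists involving KO are also given with the batch as a block. The blocked value of a KO AngII difference rests on KO PBS 4 as the link between batches.

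**Figure D1:**
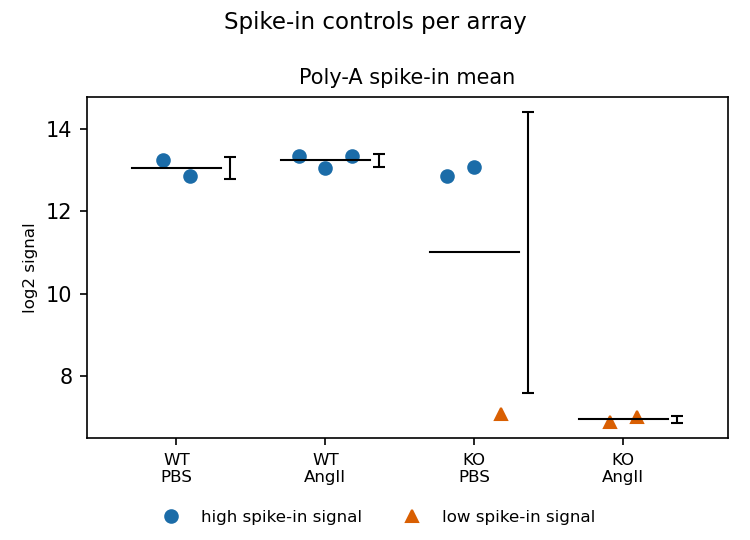
Mean log2 signal of the 24 poly-A spike-in probe sets per array, by genotype and treatment, with 1 point per array, a line at the group mean and a bar of ± 1 SD beside it. The 3 triangles, KO PBS 4 and both KO AngII arrays, lie between 6.90 and 7.08, and the 7 circles between 12.86 and 13.33.

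The first question was whether the arrays show the loss of the targeted gene. Prkcz, which encodes PKCz, read 5.70 to 5.87 on the KO arrays (5.81 ± 0.07, SD, n = 5) and 6.23 to 6.45 on the WT arrays (6.35 ± 0.09, SD, n = 5). The averaged difference was −0.53 ± 0.09, with an exact two-sided permutation p = 0.01, the smallest that 100 arrangements allow; limma's adjusted p over all probe sets was 0.126. The blocked difference was −0.60. The 2 dimmer Prkcz probe sets differed by 0.10 ± 0.09 and −0.09 ± 0.08. Where these probe sets lie relative to the deleted part is not given in the sources used here, and a probe set outside it checks nothing. For the proposed partners of PKCz, the averaged difference between KO and WT was 0.01 ± 0.10 for Mapk7, which encodes ERK5, −0.15 ± 0.14 for Map2k5, the kinase that activates ERK5, and 0.21 ± 0.12 for Sqstm1, which encodes the scaffold p62 that binds atypical PKC (blocked −0.04, 0.05 and 0.09). Gnaq, which encodes the G protein alpha-q, differed by −0.30 ± 0.12 (adjusted p = 0.378), and its 7 probe sets ranged from −0.44 to 0.25. Of the hypertrophy markers, Nppa differed by −0.26 ± 0.10 (blocked −0.14), Nppb by −0.85 ± 0.26 (−0.02), Myh7 by −0.33 ± 0.22 (−0.28) and Acta1 by 0.03 ± 0.09 (0.14), with adjusted p from 0.308 to 0.898.

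Averaged over treatments, the genotypes differed in a small number of transcripts, most of them lower in KO. Zfp931, a zinc-finger gene, fell by 1.87 ± 0.14 log2, 3.65-fold (adjusted p = 2.89e-04). A further 5 probe sets, each annotated with 4 to 8 genes, fell too; the 20 genes annotated to these 6 probe sets all lie on 1 chromosome, 19 of them within 200 genes of Zfp931, and 4 of the 6 share genes, so they are not independent findings. The leading pair, annotated with 8 and 7 genes, read 4.43 to 4.86 on KO arrays against 7.35 to 7.70 on WT arrays, and 4.82 to 5.25 against 7.82 to 8.57. Gde1, a glycerophosphodiester phosphodiesterase, fell by 1.14 ± 0.12 (adjusted p = 0.00318), Thrap3, a cofactor of splicing and transcription, by 1.19 ± 0.13 (0.00466), and Ppm1h, a protein phosphatase, by 1.07 ± 0.12 (0.00601). Sirt1, an NAD-dependent deacetylase, fell by 1.09 ± 0.16, Spry4, an inhibitor of receptor tyrosine kinase signalling, by 0.73 and Usp34, a ubiquitin protease, by 0.66 (each adjusted p = 0.0425). The Spry4 difference comes from PBS, where the means were 4.96 in KO and 6.33 in WT, against 4.93 and 5.02 under AngII. Spry4 and Usp34 were called on a dimmer probe set each, and the brightest probe set of Spry4 differed by −0.42 ± 0.10 (adjusted p = 0.251) and that of Usp34 by −0.27 ± 0.13 (0.408). Higher in KO were Cenpf, a kinetochore protein of dividing cells (1.78 ± 0.16, adjusted p = 0.00161), the uncharacterised transcript 2900052N01Rik (1.23 ± 0.18, 0.0431) and Hadh, a mitochondrial enzyme of fatty acid oxidation. Hadh rose by 0.87 ± 0.12 (0.0425) and 1.12 on a second called probe set (0.0224).

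In all, limma called 20 of 45037 probe sets, 5 higher and 15 lower in KO. An unadjusted p under 0.05 was reached by 5584, against 1410 with the batch as a block, where chance gives 2252. The 5584 became 7418 without KO PBS 3 and 4005 without KO PBS 4. With the batch as a block 5 remained called, Zfp931 (−2.04, adjusted p = 0.0342), 3 of the probe sets annotated with its neighbours and Thrap3 (−1.48, 0.04). Cenpf stood at 1.44 (0.604) and Gde1 at −1.12 (0.604). Ppm1h (−0.97), Sirt1 (−1.15), Spry4 (−0.56), Usp34 (−0.56), 2900052N01Rik (0.82) and Hadh (0.63 and 0.76) had an adjusted p of 1. The 15 probe sets that lost the call kept their direction, with a median size of 0.82 (SE 0.19) against 1.07 (SE 0.12) without the block, so at the median the calls ended with a smaller difference and a larger error. Within the high batch under PBS all 20 kept their direction, which is partly built in, as the fit that picked them used the same arrays. Zfp931, Cenpf and Gde1 were called whichever array was left out. Thrap3 lost the call without WT PBS 5 (−1.12, adjusted p = 0.0509), Ppm1h without KO AngII 4 (−1.06, 0.0747), and the second Hadh probe set without KO AngII 4, KO PBS 3, WT PBS 3 or WT PBS 5 (0.96 to 1.13). Sirt1 stayed called only without WT AngII 2 or WT AngII 3, and without any other array it lay between −0.98 and −1.20. Spry4 stayed called only without WT AngII 2 or KO PBS 3, Usp34 only without WT AngII 2, 2900052N01Rik only without KO PBS 2, WT AngII 2 or WT AngII 3, and the first Hadh probe set only without KO AngII 3 or WT AngII 2. The count was 10 without KO AngII 4, 10 without WT PBS 5 and 13 without KO PBS 4.

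**Figure D2:**
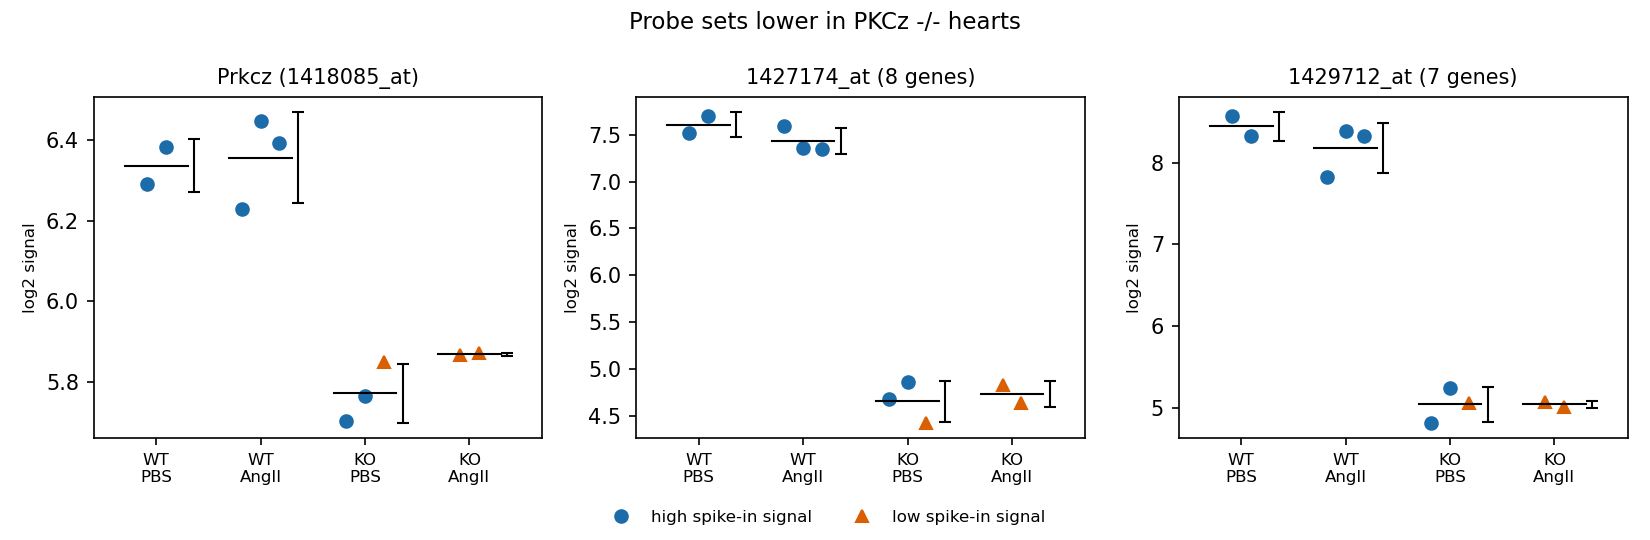
Log2 signal per array of Prkcz and of the 2 probe sets annotated with 8 and 7 genes that neighbour Zfp931, by genotype and treatment; points are arrays (circles high, triangles low spike-in signal), lines group means and bars ± 1 SD. KO arrays lie at 5.70 to 5.87, 4.43 to 4.86 and 4.82 to 5.25, below the WT arrays at 6.23 to 6.45, 7.35 to 7.70 and 7.82 to 8.57.

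Under PBS alone, 6 probe sets differed between the genotypes, 1 higher and 5 lower in KO. Cenpf rose by 2.27 ± 0.23 (adjusted p = 0.0062). Zfp931 fell by 1.86 ± 0.20 (0.008) and Spry4 by 1.38 ± 0.15 on the same dimmer probe set (0.008; −0.66 ± 0.14 on the brightest, 0.415). The 3 leading probe sets near Zfp931 differed by −3.40 to −2.55. All 6 stayed called with the block (Cenpf 2.10, Zfp931 −1.95, Spry4 −1.29), and 3 within the high batch. Under AngII 5 differed, all lower, Zfp931 (−1.87 ± 0.20, adjusted p = 0.0105), the same 3 neighbouring probe sets and an unnamed probe set (−0.75 ± 0.08, 0.0105); repeated quantile normalisation gave 1 higher and 5 lower. With the block 2 of these 5 remained called, and Zfp931 stood at −2.12 (adjusted p = 0.617). Of the 2 sets of calls, 4 probe sets were shared, all in the same direction. They are Zfp931 and the 3 neighbouring probe sets, which are not independent findings. At an unadjusted p under 0.05 stood 2835 probe sets under PBS and 2930 under AngII, with the block 2196 and 741, where chance gives 2252. The number under PBS was 4166 without KO PBS 3 and 2200 without KO PBS 4. Among the genes of smallest unadjusted p that did not pass under PBS were Ppm1h (−1.21), Gde1 (−1.08), the transcriptional regulator Ifrd1 (−0.96), the EGF receptor inhibitor Errfi1 (−2.15), Thrap3 (−1.01) and the early growth response factor Egr2 (−2.64). Under AngII they included Thrap3 (−1.36), Gde1 (−1.20), the lipolysis inhibitor G0s2 (1.10), Ppm1h (−0.92) and Cenpf (1.28). Under PBS, Cenpf lost its call without WT PBS 3 (2.15) or WT PBS 5 (2.39), Zfp931 without the same arrays (−1.81 and −1.92), and Spry4 without these (−1.41 and −1.34) or KO PBS 2 (−1.34). The count was 22 without WT AngII 2, 1 of them higher, and 14 without WT PBS 3, all lower. Under AngII, Zfp931 lost it without KO AngII 3 (−1.96), KO AngII 4 (−1.78) or WT AngII 4 (−1.88), the unnamed probe set without the same arrays (−0.68, −0.82 and −0.77). The count was then 8 without KO AngII 3, 5 higher and 3 lower, and 8 without KO PBS 4, 1 higher and 7 lower.

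For the genes chosen beforehand, the KO minus WT difference under PBS was −0.56 ± 0.13 for Prkcz (blocked −0.60), 0.04 ± 0.14 for Mapk7 (0.02), −0.02 ± 0.20 for Map2k5 (0.08), −0.24 ± 0.17 for Gnaq (−0.22) and 0.16 ± 0.18 for Sqstm1 (0.10). It was −0.37 ± 0.15 for Nppa (−0.31), −1.50 ± 0.36 for Nppb (−1.08), −0.25 ± 0.31 for Myh7 (−0.22) and 0.03 ± 0.13 for Acta1 (0.08), with adjusted p from 0.437 to 0.992. Under AngII it was −0.49 ± 0.13 for Prkcz (−0.60), −0.01 ± 0.14 for Mapk7 (−0.09), −0.29 ± 0.20 for Map2k5 (0.01), −0.36 ± 0.17 for Gnaq (−0.30) and 0.25 ± 0.18 for Sqstm1 (0.07). The markers then stood at −0.14 ± 0.15 for Nppa (0.03), −0.19 ± 0.36 for Nppb (1.04), −0.41 ± 0.31 for Myh7 (−0.34) and 0.03 ± 0.13 for Acta1 (0.20), with adjusted p from 0.734 to 0.983.

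As a group, immediate early genes, the transcription factors and feedback regulators induced within minutes of a stimulus, fell in KO under PBS. Of 25 members 24 lay below 0 with a median of −0.88 (camera adjusted p = 1.89e-17). The leading members were Egr2 (−2.64 ± 0.49), the Kruppel-like factor Klf6 (−1.10 ± 0.23), the antiproliferative Btg2 (−1.95 ± 0.42) and Egr1 (−1.95 ± 0.43). Adjusted over the list alone 15 fell, against 0 over all genes. The 2 WT PBS arrays stood 0.55 and 0.98 above the mean of all arrays and the other 8 between −0.70 and 0.19. Their 18S ribosomal RNA signal was also the highest, 9.16 on WT PBS 3 and 8.07 on WT PBS 5 against 6.60 to 8.01. The 3' minus 5' signal of beta-actin was 1.17 and 1.70 there and 0.74 to 1.38 elsewhere. Hypertrophic marker genes fell as well, 18 of 21 below 0 with a median of −0.35 (1.46e-07). Among them were the smooth muscle actin Acta2 (−0.77 ± 0.15), the sarcomere-linked repressor Ankrd1 (−0.42 ± 0.08), the intercalated disc protein Xirp1 (−1.21 ± 0.28) and the natriuretic peptide gene Nppb (−1.50 ± 0.36). In this list 7 genes fell adjusted over the list alone and 0 over all genes. All 12 measured members of the protein kinase C family lay below 0 (median −0.22, 0.00294), led by Prkcz (−0.56 ± 0.13) and its close relative Prkci (−0.46 ± 0.24). Only 1, Prkcz, passed adjusted over the list alone. Inflammatory cytokines and NF-kB targets (−0.32), smooth muscle and pericyte markers (−0.21), macrophage markers (−0.32) and extracellular matrix genes (−0.20) completed the 7 lists called, all lower. Adjusted over the list alone 0, 1 (Acta2), 0 and 1 (Ccn2, −1.81 ± 0.41) fell, and 0 over all genes.

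None of these 7 calls held with an estimated correlation (adjusted p = 0.467 for immediate early genes, 0.692 to 0.839 for the others). With the block, equal to the high-batch value under PBS, the medians were −0.61 for immediate early genes, −0.25 for hypertrophic markers, −0.17 for the protein kinase C family, −0.26 for NF-kB targets and −0.25 for smooth muscle, all called. Matrix genes (−0.12, adjusted p = 0.216) and macrophage markers (−0.24, 0.0563) lost the call. Immediate early genes stayed called whichever array was left out. Hypertrophic markers lost the call without WT PBS 3 (−0.19) and stood at −0.55 without WT PBS 5. NF-kB targets lost it without WT PBS 3 (−0.17), and the protein kinase C family lost it without WT PBS 5 (−0.17) and stood at −0.36 without KO PBS 3. Smooth muscle lost it without WT PBS 5 (−0.11) or KO PBS 3 (−0.24) and stood at −0.45 without WT PBS 3. Macrophage markers lost it without WT PBS 5 (−0.18), KO PBS 3 (−0.33) or KO PBS 4 (−0.24), and so did matrix genes (−0.06, −0.25 and −0.12).

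Under AngII 8 lists differed between the genotypes, and without WT AngII 2 only oxidative phosphorylation kept its call and direction. Genes of fatty acid uptake and oxidation rose in KO relative to WT, 27 of 31 above 0 with a median of 0.17 (camera adjusted p = 2.26e-05). Hadh (0.92 ± 0.17), the very-long-chain dehydrogenase Acadvl (0.33 ± 0.12) and Pdk4, the kinase that holds back pyruvate oxidation (0.86 ± 0.35), led the list. Only 1, Hadh, passed adjusted over the list alone and 0 over all genes. Genes of oxidative phosphorylation rose, 37 of 39 above 0 with a median of 0.12 (4.47e-07), led by Sdhb of complex II (0.23 ± 0.08), Cox6c of complex IV (0.21 ± 0.08), Ndufb3 of complex I (0.28 ± 0.11) and, against the direction, Ndufa4 (−0.25 ± 0.10), with 0 passing adjusted over the list alone or over all genes. Extracellular matrix genes fell, 42 of 43 below 0 with a median of −0.42 (6.02e-04), led by the matricellular Ccn2 (−1.30 ± 0.41) and the protease inhibitor Timp2 (−0.45 ± 0.23), but turned to 0.29 (3.96e-08) without WT AngII 2. Macrophage markers fell (−0.31, 0.03), led by the scavenger receptor Cd163 (−0.66 ± 0.26) and the growth factor receptor Csf1r (−0.68 ± 0.29), and 0 genes of either list passed adjusted over the list alone or over all genes. Immediate early genes fell by a median of 0.32 (0.0238), led by Klf6 (−0.83 ± 0.23) and the phosphatase Dusp6 (−1.30 ± 0.39). The protein kinase C family fell by 0.23 (0.0184), led by Prkcz (−0.49 ± 0.13), and smooth muscle markers by 0.19 (0.03), led by Acta2 (−0.51 ± 0.15). Heat shock genes rose by 0.21 (0.0472), led by the chaperonin Hspe1 (0.46 ± 0.14). Adjusted over the list alone Prkcz passed in these 4 lists and no other gene, and 0 passed over all genes.

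Each of these 8 lists had an adjusted p of 0.832 or 0.837 with an estimated correlation. The array WT AngII 2 stood apart: its matrix genes lay 2.02 above the mean of all arrays, and those of the other 9 arrays between −0.68 and 0.10. Without it the matrix difference turned to 0.29 (adjusted p = 3.96e-08) and the macrophage difference to 0.16 (0.169). Oxidative phosphorylation remained called at 0.05 (0.00675), and the calls of fatty acid oxidation (0.08, 0.0566), heat shock (0.19, 0.0566), smooth muscle (−0.10, 0.253), the protein kinase C family (−0.08, 0.11) and immediate early genes (−0.17, 0.0872) ended. With the batch as a block fatty acid oxidation (0.24), oxidative phosphorylation (0.07, 0.0421), heat shock (0.41) and smooth muscle (−0.24, 0.0402) stayed called. Immediate early genes turned to 0.24 (0.00483), and matrix genes (−0.19), macrophage markers (−0.17) and the protein kinase C family (−0.06) lost the call. Other arrays left out also ended calls: KO AngII 3 for heat shock and macrophage markers (0.21 and −0.22), and KO AngII 4 for heat shock, smooth muscle and immediate early genes (0.21, −0.19 and −0.28). KO PBS 3 did so for heat shock, smooth muscle and macrophage markers (0.21, −0.19 and −0.31), WT AngII 3 for heat shock (0.17) and WT AngII 4 for immediate early genes (−0.20). Without WT AngII 3 the medians of matrix genes, macrophage and smooth muscle markers were −0.89, −0.55 and −0.33. Without WT AngII 4 those of matrix genes, macrophage markers, the protein kinase C family and fatty acid oxidation were −0.81, −0.49, −0.35 and 0.25.

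Averaged over treatments, 11 lists differed between KO and WT, 2 higher and 9 lower. Fatty acid genes rose in KO, 29 of 31 above 0 with a median of 0.12 (camera adjusted p = 3.07e-04). In this list 2 genes, Hadh and the mitochondrial uncoupling protein Ucp3 (1.09 ± 0.22), passed adjusted over the list alone, against 1 over all genes. Smooth muscle and pericyte markers fell, 13 of 14 below 0 with a median of −0.24 (0.00241), among them Acta2 (−0.64 ± 0.10), the only 1 adjusted over the list alone, the pericyte regulator Rgs5 (−0.23 ± 0.08) and the pericyte receptor Pdgfrb (−0.49 ± 0.19), with 0 over all genes. Immediate early genes fell by a median of 0.65 (1.6e-09), led by Klf6 (−0.96 ± 0.16) and Egr1 (−1.66 ± 0.30), 14 of them adjusted over the list alone and 0 over all genes. Genes of the ERK5 module and atypical PKC partners fell by 0.13 (0.0469), led by the ERK5 pathway kinase Map3k2 (−0.51 ± 0.17) and the phospholipase Plcb4 (−0.25 ± 0.09), with 0 passing either way. The adjusted p was 0.631 with an estimated correlation for all of these. With the block, fatty acid genes (0.19) and smooth muscle markers (−0.22) stayed called, immediate early genes (−0.06, adjusted p = 0.0609) and the ERK5 module (−0.01, 0.704) did not. Without WT AngII 2 fatty acid genes stood at 0.07 and smooth muscle at −0.15, both called. The ERK5 module lost its call without any of WT AngII 2 (−0.08), WT PBS 5 (−0.08), KO PBS 4 (−0.10), KO AngII 4 (−0.13), KO PBS 2 (−0.13) or WT PBS 3 (−0.15).

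In the average over treatments, hypertrophic markers were lower in KO by a median of 0.26 (camera adjusted p = 2.7e-04). Adjusted over the list alone 6 passed, Acta2 (−0.64 ± 0.10), the calcineurin regulator Rcan1 (−1.11 ± 0.28) and Ankrd1 (−0.21 ± 0.06) among them, and 0 over all genes. The list was called under PBS but not under AngII, and its AngII effect was higher in KO by a median of 0.25. The average therefore does not show lower markers in KO under AngII. Matrix genes fell by 0.33 (6.26e-04), led by Ccn2 (−1.56 ± 0.29), the 1 gene that passed adjusted over the list alone, and Thbs1 (−1.33 ± 0.41). Macrophage markers fell by 0.36 (0.00642), led by Cd163 (−0.58 ± 0.18) and Csf1r (−0.50 ± 0.20), with 0 passing either way. Their adjusted p with an estimated correlation was 0.631, and 0.761 for matrix genes. With the block hypertrophic markers stayed called at −0.18 (0.0481), while matrix genes stood at −0.15 (0.252) and macrophage markers at −0.23 (0.0609). Hypertrophic markers lost the call without WT PBS 3 (−0.17) and stood at −0.41 without WT PBS 5. Without WT AngII 2 matrix genes turned to 0.09 (0.695) and macrophage markers lost the call (−0.09), and without WT AngII 3 or WT AngII 4 matrix genes stood at −0.51.

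In WT hearts, AngII was compared with PBS as the model of hypertrophy. Extracellular matrix genes rose, 39 of 43 above 0 with a median of 0.80 (camera adjusted p = 2.98e-11), led by the collagen-binding Sparc (1.10 ± 0.40), the microfibril protein Mfap5 (1.51 ± 0.60) and the proteoglycan Bgn (1.07 ± 0.43), but without WT AngII 2 their median was 0.09 (0.172). Fibroblast markers rose with them, 13 of 14 above 0 with a median of 0.61 (2.91e-07), such as Pi16 (0.86 ± 0.31) and the proteoglycan Lum (1.03 ± 0.37). Macrophage markers rose by 0.30 (0.0093), such as Csf1r (0.56 ± 0.29) and the lysozyme Lyz2 (0.50 ± 0.33), and stood at −0.05 (0.368) without WT AngII 2. Fatty acid genes fell, all 31 below 0 with a median of −0.26 (1.51e-11), led by Pdk4 (−1.41 ± 0.35), Acadvl (−0.44 ± 0.12) and the thioesterase Acot1 (−0.63 ± 0.19). Oxidative phosphorylation genes fell by 0.12 (1.2e-07), such as Ndufv1 of complex I (−0.34 ± 0.10) and Sdha of complex II (−0.34 ± 0.14), and stood at −0.05 (0.123) without WT AngII 2. In these 5 lists 0 genes passed adjusted over the list alone or over all genes. Immediate early genes fell, 23 of 25 below 0 with a median of −0.69 (1.76e-13), with Egr2 (−2.07 ± 0.49), Btg2 (−1.75 ± 0.42), the stress factor Atf3 (−2.60 ± 0.64) and Egr1 (−1.71 ± 0.43). In this list 11 genes fell adjusted over the list alone and 0 over all genes. NF-kB targets fell by a median of 0.21 (0.00122), led by the cytokine feedback inhibitor Socs3 (−1.66 ± 0.55) and the chemokine Cxcl12 (−0.51 ± 0.17), with 0 passing either way. Cell cycle genes rose by 0.11 (0.00833), led by Kif20a, a mitotic kinesin (0.48 ± 0.11), and the kinase Cdk1 (0.43 ± 0.16). Kif20a passed adjusted over the list alone and 0 genes over all genes.

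Of the markers of pathological growth, the natriuretic peptide gene Nppa differed by 0.58 ± 0.15 (0.41 without WT AngII 2) and skeletal actin, Acta1, by 0.43 ± 0.13 in WT (0.22 without WT PBS 5). The fetal myosin Myh7 differed by 0.41 ± 0.31, but by 0.09 without WT PBS 5, 0.15 without WT AngII 2, 0.62 without WT AngII 3 and 0.73 without WT PBS 3. Nppb differed by −0.66 ± 0.36 (adjusted p from 0.877 to 0.93 for these 4). The brightest probe set of the adult myosin Myh6 read 14.32 to 14.49 on all arrays, near the highest value of 14.68, so its differences cannot show a change; a dimmer one differed by −0.49 ± 1.04. Nppa reached 14.48 on WT AngII 2 and 13.07 to 14.05 on the other arrays, so its difference is possibly compressed. Adjusted over the hypertrophic list alone Nppa rose and Xirp1 fell (−1.19 ± 0.28), both at 0.0202, and 0 passed over all genes. Mapk7 differed by 0.21 ± 0.14, Map2k5 by −0.05 ± 0.20 (0.44 ± 0.18 on a dimmer probe set), Gnaq by −0.05 ± 0.17, Sqstm1 by 0.23 ± 0.18 and Prkcz by 0.02 ± 0.13. Among the single genes of smallest unadjusted p were Ifrd1 (−1.05 ± 0.15), the amylase Amy1 (−1.06 ± 0.17), the secreted protease Adamts1 (−1.58 ± 0.30), Errfi1 (−1.78 ± 0.34), the detoxifying enzyme Glo1 (−0.68 ± 0.13) and the deubiquitinase Otud1 (−2.11 ± 0.46). Limma called 0 probe sets (smallest adjusted p = 0.069); 2356 had an unadjusted p under 0.05, against 5063 without WT AngII 2 and 1308 without WT PBS 5, where chance gives 2252. The count of calls was 3 without WT AngII 2 and 1 without KO PBS 3, WT PBS 3 or WT PBS 5.

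The 3 other lists called in WT fell, adult contractile and calcium handling genes by a median of 0.10 (camera adjusted p = 0.0301), ion channels and connexins by 0.07 (0.0197) and insulin signalling by 0.21 (0.0301), with 0 genes passing adjusted over the list alone or over all genes. All 11 lists called in WT, 4 higher and 7 lower, had an adjusted p of 0.655 with an estimated correlation. Without WT AngII 2, 6 of them lost the call: matrix genes, macrophage markers, oxidative phosphorylation, adult contractile genes (−0.04, 0.335), ion channels (−0.15, 0.172) and insulin signalling (−0.19, 0.0934), while fibroblast markers (0.31, 0.00445), fatty acid genes (−0.15, 2.89e-04) and NF-kB targets (−0.43) stayed called. On that array the matrix genes exceeded the mean of WT AngII 3 and 4 by a median of 2.15, fibroblast markers by 1.19 and macrophage markers by 1.22, against 0.45 for atrial cardiomyocyte, 0.37 for smooth muscle, 0.12 for endothelial and −0.07 for ventricular and general cardiomyocyte markers. Macrophage markers lost the call without WT PBS 3 (0.25), NF-kB targets without WT PBS 3 (−0.09), and cell cycle genes without WT AngII 3 (0.12) or WT PBS 5 (0.11). Contractile genes lost it without WT PBS 3 (−0.09) or KO PBS 3 (−0.10), ion channels without WT PBS 5 (−0.06), and insulin signalling without WT AngII 3 (−0.13) or WT PBS 5 (−0.09). Ion channels stood at −0.12 without WT AngII 4 and −0.16 without WT PBS 3. Without WT AngII 3 matrix genes stood at 1.29, macrophage markers at 0.55 and NF-kB targets at −0.14; without WT AngII 4 macrophage markers stood at 0.48 and NF-kB targets at −0.14, and without WT PBS 5 NF-kB targets at −0.31.

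**Figure D3:**
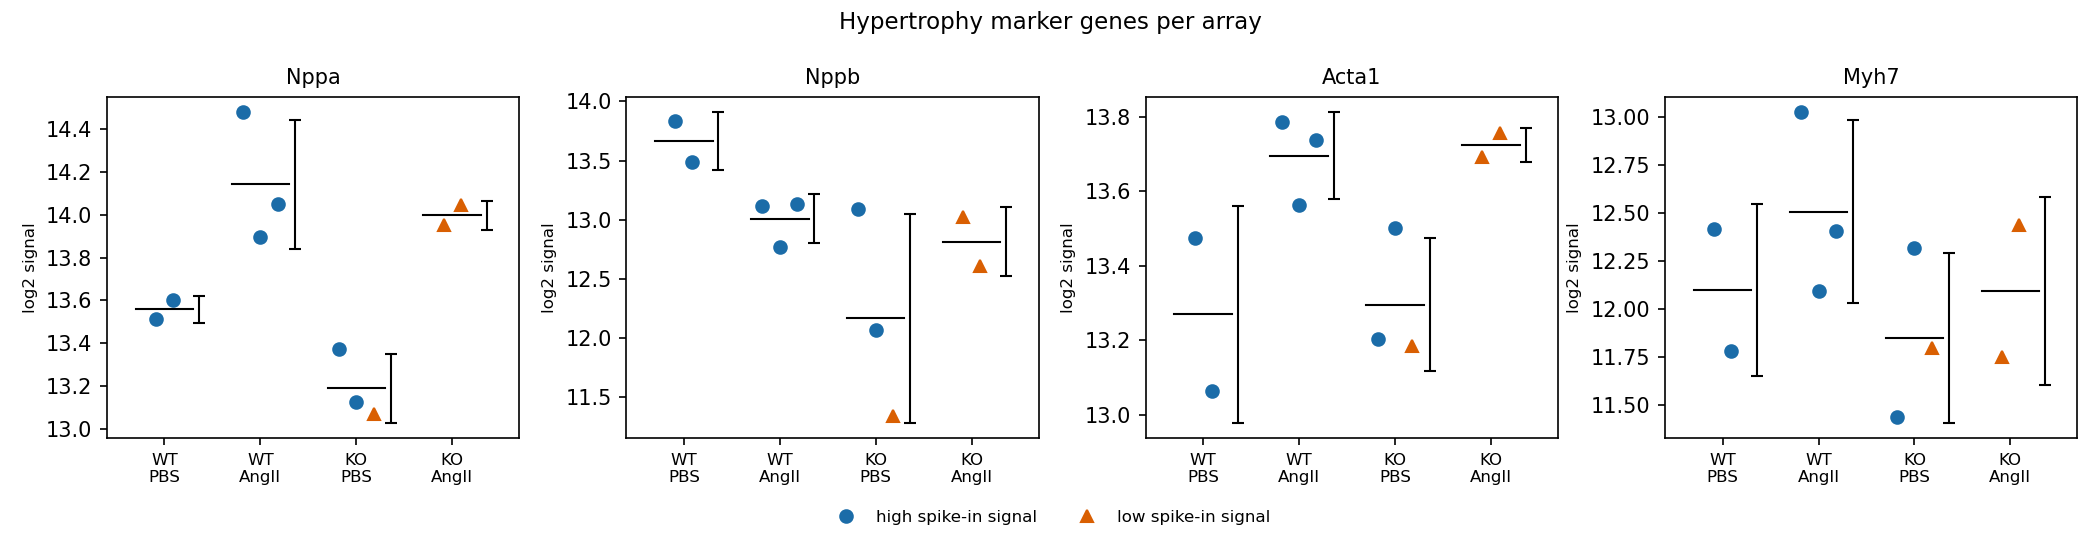
Log2 signal per array of Nppa, Nppb, Acta1 and Myh7 by genotype and treatment, with circles for arrays of high and triangles for arrays of low spike-in signal, lines at group means and bars of ± 1 SD. The means of Nppa were 13.56 in WT PBS, 14.14 in WT AngII, 13.19 in KO PBS and 14.00 in KO AngII.

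In KO hearts, matrix and hypertrophy genes stood higher under AngII than under PBS as lists. Both KO AngII arrays were of low and 2 of the 3 KO PBS arrays of high spike-in signal, so treatment and batch are largely mixed here. Matrix genes rose, 41 of 43 above 0 with a median of 0.55 (camera adjusted p = 2.1e-07), led by Mfap5 (1.70 ± 0.60), periostin, Postn (1.88 ± 0.81), the fibrillar collagen Col3a1 (1.42 ± 0.63) and Sparc (0.87 ± 0.40). Fibroblast markers rose by 0.46 (4.02e-04), led by Col3a1 and the proteoglycan Dcn (0.36 ± 0.19). Hypertrophic marker genes rose, 17 of 21 above 0 with a median of 0.16 (1.29e-04). Nppa (0.81 ± 0.15), Ankrd1 (0.38 ± 0.08) and Acta1 (0.43 ± 0.13) were the 3 that passed adjusted over the list alone, and 0 passed over all genes. Fatty acid genes fell, 29 of 31 below 0 with a median of −0.22 (5.16e-05), led by the reductase Decr1 (−0.50 ± 0.18), the lipase inhibitor Angptl4 (−1.16 ± 0.44) and Ucp3 (−0.81 ± 0.31). Macrophage markers rose by 0.31 (0.0146), led by the mannose receptor Mrc1 (0.31 ± 0.18) and Lyz2 (0.55 ± 0.33), while Cd163 stood at −0.38 ± 0.26. In the lists other than the hypertrophic 1, 0 genes passed adjusted over the list alone or over all genes. Prkcz differed by 0.10 ± 0.13 (blocked 0.02), Myh7 by 0.24 ± 0.31 (0.30), Nppb by 0.65 ± 0.36 (1.47), Mapk7 by 0.15 ± 0.14 (0.10), Map2k5 by −0.32 ± 0.20 (−0.12), Gnaq by −0.17 ± 0.17 (−0.13) and Sqstm1 by 0.32 ± 0.18 (0.20), with adjusted p from 0.892 to 0.918. The dimmer Myh6 probe set differed by 2.27 ± 1.04, and by −0.50 with the block. Among the single genes of smallest unadjusted p, besides Nppa, were Rbmxl2 (−0.88 ± 0.15), Cenpf (−1.24 ± 0.23), the Rab regulator Tbc1d10c (−0.78 ± 0.16) and the pro-apoptotic Bcl2l11 (−1.16 ± 0.28).

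Limma called 0 probe sets in KO (smallest adjusted p = 0.892), and 2060 had an unadjusted p under 0.05, 4744 without KO PBS 4, 888 without KO PBS 3 and 409 with the block, where chance gives 2252. Without KO AngII 3 the count was 3 and without KO AngII 4 it was 1. The lists had an adjusted p of 0.86 with an estimated correlation. With the block, where the difference is that within the low batch between KO AngII 3 and 4 and the lone KO PBS 4, matrix genes stood at 0.75, fibroblast markers at 0.45, hypertrophic markers at 0.32, fatty acid genes at −0.18 and macrophage markers at 0.31, all called. Macrophage markers lost the call without KO AngII 4 (0.21) or KO PBS 4 (0.22), hypertrophic markers stood at 0.30 without KO AngII 3, and fatty acid genes at −0.13 without KO PBS 3.

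Averaged over genotypes, matrix and fibroblast genes stood higher and fatty acid genes lower under AngII than under PBS. Matrix genes rose by a median of 0.62 (camera adjusted p = 6.62e-12), with Mfap5 at 1.61 ± 0.42, Sparc at 0.98 ± 0.28 and Postn at 1.94 ± 0.58. Fibroblast markers rose by 0.54 (4.81e-07), where 8 members, Lum (0.83 ± 0.26) and Col3a1 (1.38 ± 0.45) among them, passed adjusted over the list alone. All 31 fatty acid genes lay below 0 (median −0.23, 1.45e-10), and 6 passed adjusted over the list alone, including Pdk4 (−1.02 ± 0.24), Acaa2 of beta-oxidation (−0.40 ± 0.11) and Decr1 (−0.47 ± 0.13). Immediate early genes fell by a median of 0.57 (2.49e-07), 9 of them adjusted over the list alone, led by Egr1 (−1.41 ± 0.30) and Btg2 (−1.06 ± 0.30). No member of the matrix list passed adjusted over the list alone, and 0 members of these 4 lists passed over all genes. The single genes with the smallest unadjusted p were Nppa (0.70 ± 0.10), the membrane protein Tmem47 (−0.63 ± 0.10), the noncoding RNA Snhg14 (−1.01 ± 0.17), Ppm1h (−0.66 ± 0.12) and the phosphorylase kinase subunit Phkg1 (−0.60 ± 0.12). Acta1 differed by 0.43 ± 0.09 (each adjusted p = 0.483; blocked 0.76 for Nppa and 0.48 for Acta1).

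The other genes chosen beforehand differed by 0.33 ± 0.22 for Myh7 (blocked 0.35), 0.00 ± 0.26 for Nppb (0.41), 0.06 ± 0.09 for Prkcz (0.02), 0.18 ± 0.10 for Mapk7 (0.15), −0.19 ± 0.14 for Map2k5 (−0.09), −0.11 ± 0.12 for Gnaq (−0.09) and 0.28 ± 0.12 for Sqstm1 (0.22), with adjusted p from 0.516 to 0.997. The dimmer Myh6 probe set differed by 0.89 ± 0.73 (−0.50).

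Limma called 0 probe sets for this average (smallest adjusted p = 0.304), with 4334 at an unadjusted p under 0.05 where chance gives 2252. This number was 1331 with the block, 2229 without WT PBS 5 and 7857 without WT AngII 2. The count of calls was 2 without KO AngII 3 and 1 without KO AngII 4, WT PBS 3 or WT PBS 5. With an estimated correlation matrix genes had an adjusted p of 0.737 and the other 3 lists 0.706. With the block the medians were 0.79 for matrix genes, 0.58 for fibroblast markers, −0.22 for fatty acid genes and −0.27 for immediate early genes, all called. Without WT AngII 2 matrix genes stood at 0.29 (1.2e-10). Across 18193 genes, which are not independent replicates, the AngII effects in WT and in KO correlated with Pearson r = 0.49 and Spearman rho = 0.49, and 66.8% had the same sign; no array is shared between these effects. With the block r was 0.24, and 0.0986 when WT AngII 2 was left out as well; the title number as a block gave 0.174.

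Whether PKCz changes the response to AngII was tested by the difference of the effects, KO minus WT. Immediate early genes had the higher AngII effect in KO, 22 of 25 above 0 with a median difference of 0.53 (camera adjusted p = 1.09e-09), as Egr2 (2.18 ± 0.69) and Atf3 (2.39 ± 0.90) show. As a list they fell under AngII in WT and were not called in KO, so the difference is not a called rise in KO. Hypertrophic marker genes had a median difference of 0.25 (7.44e-05), with Ankrd1 (0.43 ± 0.12), Xirp1 (1.20 ± 0.39), Nppb (1.30 ± 0.51) and the actin regulator Enah (0.63 ± 0.25). Heat shock genes had 0.24 (2.91e-04), led by Hsp90aa1 (0.55 ± 0.23). In these 3 lists 0 genes passed adjusted over the list alone or over all genes. These differences share the WT PBS arrays with the falls of immediate early genes in WT under AngII and in KO under PBS, so the 3 results are not independent. For single markers the difference was 0.23 ± 0.21 for Nppa (0.39 without WT AngII 2), where a ceiling on WT AngII 2 would raise the value, 0.00 ± 0.19 for Acta1, −0.16 ± 0.44 for Myh7, −0.05 ± 0.19 for Mapk7, −0.27 ± 0.28 for Map2k5, −0.12 ± 0.24 for Gnaq and 0.09 ± 0.25 for Sqstm1 (blocked 0.34, 0.11, −0.11, −0.10, −0.07, −0.08 and −0.03). A dimmer probe set of Gnaq differed by 0.47 ± 0.27 (blocked 0.09), and that of Myh6 by 2.77 ± 1.47 (−0.01). Prkcz differed by 0.08 ± 0.18 (0.00). The genes with the smallest unadjusted p were the glutathione transferase Mgst1 (1.22 ± 0.23), Ifrd1 (1.06 ± 0.21), Adamts1 (1.92 ± 0.42), Rbmxl2 (−0.92 ± 0.21) and Errfi1 (1.93 ± 0.48).

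Limma called 0 probe sets for this difference (smallest adjusted p = 1), and 737 had an unadjusted p under 0.05, 520 higher and 217 lower, and 1551 without WT AngII 2, where chance gives 2252. The count of calls was 2 without KO AngII 3 and 1 without KO AngII 4 or WT PBS 5. With an estimated correlation the 3 lists had an adjusted p of 0.794. With the block the KO effect sets KO AngII 3 and 4 against the lone KO PBS 4, so the values rest on that array. Immediate early genes then stood at 0.89, hypertrophic markers at 0.11 and heat shock genes at 0.49, all called, and Nppb differed by 2.13. Without WT PBS 3 hypertrophic markers stood at 0.02 (0.432) and heat shock genes at 0.14 (0.0905). Values without KO PBS 4 were 0.17 (0.0975) for heat shock and 0.33 for immediate early genes, and without KO PBS 2 heat shock genes stood at 0.38.

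**Figure D4:**
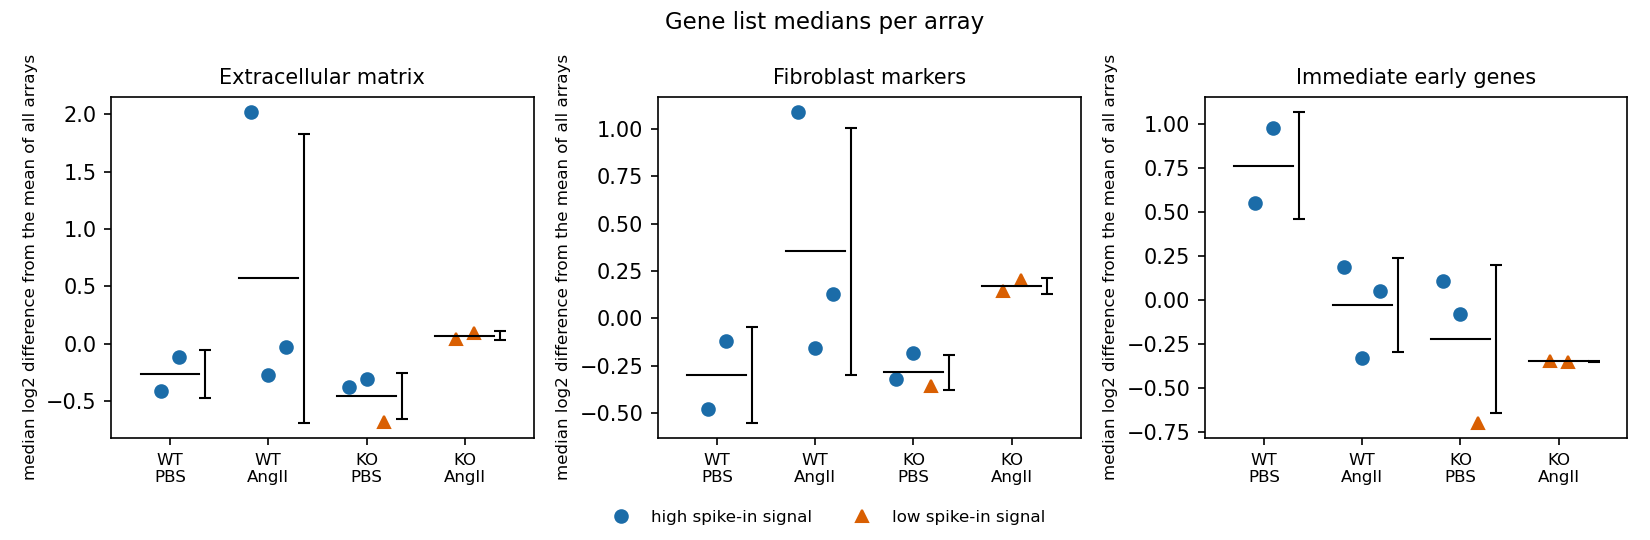
Median over the members of the matrix, fibroblast and immediate early lists of the log2 difference from the mean of all 10 arrays, per array, with group means as lines and bars of ± 1 SD; circles have high and triangles low spike-in signal. WT AngII 2 stands at 2.02 in the matrix list, and WT PBS 3 and 5 stand at 0.55 and 0.98 in the immediate early list.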

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

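The tests of possible causes in this part were chosen after the result was seen, and the 1 on heat shock genes replaced an earlier version that rested on 1 array; the list tests and the omission of single arrays were fixed before. The poly-A spike-in signal differed by 6.11 log2, 69.3-fold, between 3 arrays and the other 7; spike-in batches, hybridisation dates and amounts of control RNA are not given in the sources used here.

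Beside the immediate early (0.53), hypertrophic (0.25) and heat shock genes (0.24), the AngII effect was higher in KO than in WT for 5 further lists, each with 0 genes passing adjusted over the list alone and 0 over all genes. A higher effect need not be a rise, as fatty acid genes fell under AngII in both genotypes. Oxidative phosphorylation, 37 of 39 genes above 0, had a median of 0.10 (camera adjusted p = 4.49e-05), and without WT AngII 2 it was 0.03 (0.297). Inflammatory cytokines and NF-kB targets, with the chemokine Cxcl12 at 0.46 ± 0.24 and Ccl5 at 0.46 ± 0.25, had 0.20 (0.00287); the call was lost without KO PBS 4 (0.21), WT AngII 3 (0.10), WT AngII 4 (0.14) or WT PBS 3 (0.08), and the median was 0.31 without KO PBS 3, 0.53 without WT AngII 2 and 0.40 without WT PBS 5. Fatty acid genes had 0.10 (0.0289), called only without KO PBS 3, WT AngII 3 or WT AngII 4 (0.19), and −0.02 without WT AngII 2. Cardiomyocyte markers, which share 7 genes with the contractile list, had 0.0895 (0.0289) and lost the call without KO AngII 3 (0.08), KO PBS 2 (0.07), KO PBS 4 (0.08), WT AngII 2 (0.04) or WT PBS 3 (0.07). Adult contractile and calcium handling genes had 0.074 (0.0342), called only without KO AngII 4, WT AngII 3 or WT AngII 4, and 0.04 without WT AngII 2. With an estimated correlation the adjusted p was 0.987 for fatty acid genes and 0.794 for the other lists; with the block NF-kB targets (0.26, 0.00207) and fatty acid genes (0.13, 0.0434) stayed called.

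Immediate early genes stood high on both WT PBS arrays, and these arrays enter their fall in WT under AngII, their fall in KO under PBS and their higher AngII effect in KO. A batch that follows the spike-in level would leave no difference among arrays of high spike-in signal. Yet there the KO minus WT median under PBS was −0.61 (camera adjusted p = 9.59e-16 at the preset correlation), with 24 of 25 genes below 0. This argues against such a batch as the sole cause. It does not exclude it, as the test was chosen after the result and reuses the WT PBS arrays that stood high. A difference there was therefore partly built in. With the estimated correlation over all arrays no list was called under PBS (smallest camera adjusted p = 0.467). Labelling that varied among the high arrays is not covered by this test. Their 3' minus 5' signal of beta-actin ran from 0.92 to 1.70, highest on WT PBS 5. Handling stress that also induces heat shock genes could raise them in 2 hearts; the heat shock median was −0.15 (0.227), which leaves this open. The state of the RNA also stays open, as 18S signal was highest on the same 2 arrays (9.16 and 8.07, elsewhere up to 8.01). A biological reading, in which PKCz sustains early gene expression at rest, is likewise open with 2 WT PBS arrays. RNA integrity and time from death to freezing, recorded per heart, or early gene transcripts in further PBS hearts would tell these apart.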

How the results depend on the processing

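Values follow the named alternative; the cause of each move was not tested. Every call of a list is lost with an estimated correlation. Leaving out 1 array gave 0 to 3 calls for AngII in WT and in KO, 0 to 2 for their difference and for averaged AngII, 4 to 22 for KO against WT under PBS, 4 to 8 under AngII and 10 to 30 averaged. It gave r from 0.329 (without WT PBS 5) to 0.519 (without WT PBS 3) for the AngII effects, and 55 (without WT AngII 2) to 74 of 252 list tests called, where all arrays gave 64; WT AngII 2 alone ended 24 of these 64. Where the array left out leaves a group of 1, that array is assumed to vary like the other groups. No pairing by title number was seen (10 pairs of equal number, median residual r 0.0089, range −0.36 to 0.10). Residuals within groups of 2 or 3 arrays mirror each other, so this check could hardly show it. The replicate block therefore serves as a stress test.

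Array weights gave 262 calls for AngII in WT, 18 for KO against WT under PBS, 2911 under AngII, 90 for averaged AngII, 1562 for averaged KO against WT and 42 list tests. These weights, estimated from 10 arrays, ranged from 0.225 to 7.20, and their stability was not tested. Both extremes lay in WT AngII, with 7.20 for WT AngII 4, 0.652 for WT AngII 3 and 0.225 for WT AngII 2. The weighted mean of that group, and the counts that use it, therefore rest largely on WT AngII 4. The replicate block gave 1, 3, 3, 5 (AngII in WT, KO against WT under PBS, under AngII, averaged) and r = 0.174. The spike-in block gave 2 for KO against WT under AngII, 5 averaged and r = 0.24. The spike-in block without WT AngII 2 gave 20 for AngII in WT, 17 for KO against WT under PBS, 2 under AngII, 2 for averaged AngII, 6 for averaged KO against WT and r = 0.0986. Without WT AngII 2 and WT PBS 5 the counts were 11 for AngII in WT, 8 in KO, 2 for their difference, 27 for KO against WT under PBS and 14 for averaged AngII. Robust eBayes gave 1 for AngII in WT. Only the 5 arrays compared gave 2 for AngII in KO, and the low batch alone 36, on 1 residual degree of freedom. The high batch alone gave 3 for KO against WT under PBS. Probe sets at or above the median gave 3 for KO against WT under AngII and 13 averaged, and eBayes without trend 13 averaged.

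Lists whose direction reversed: macrophage markers for AngII in WT, −0.0492 without WT AngII 2 (−0.0492 to 0.55 over single arrays), −0.0492 with the spike-in block as well, and −0.0027 without WT PBS 5 as well. For the difference of AngII effects, fatty acid genes were −0.0175 with array weights, −0.0804 with the replicate block, −0.019 without WT AngII 2 (−0.019 to 0.19 over single arrays), 0.0121 with the spike-in block as well and −0.0126 without WT PBS 5 as well, and oxidative phosphorylation 0.0076 with the spike-in block without WT AngII 2. For KO against WT under AngII, matrix genes were 0.14 with array weights, 0.29 without WT AngII 2 (−0.89 to 0.29 over single arrays), 0.62 with the spike-in block as well and 0.29 without WT PBS 5 as well, and macrophage markers 0.085, 0.16 (−0.55 to 0.16), 0.20 and 0.16. With the spike-in block without WT AngII 2 the protein kinase C family was 0.0667, immediate early genes 0.44 (0.24 with the spike-in block alone) and oxidative phosphorylation −0.0041. For averaged KO against WT, matrix genes were 0.0887 without WT AngII 2 (−0.51 to 0.0887 over single arrays), 0.26 with the spike-in block as well and 0.0694 without WT PBS 5 as well; the ERK5 module was 0.0393 with the spike-in block without WT AngII 2, and insulin signalling 0.0568 with the spike-in block and 0.0371 without WT AngII 2 as well. The sign is that of camera, which the median of a few does not share.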

Other observations

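The tests of possible causes in this part were chosen after the result was seen, apart from 3 written before: the regrouping of arrays for AngII, the neighbours of Prkcz and the genes around Zfp931. The list tests and the omission of single arrays were fixed before the data were examined. The wording for the regrouping of genotypes was corrected after its result, with the limit of 5 in 100 unchanged.

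Averaged over genotypes, clock genes were also lower under AngII, 15 of 18 below 0 with a median of −0.19 (camera adjusted p = 0.00538). The repressors Cry1 (−0.44 ± 0.13), Per1 (−0.68 ± 0.21) and Cry2 (−0.30 ± 0.10) led the list. In KO alone the median was −0.26 (0.00148), led by Hlf (−0.80 ± 0.24), and −0.11 (0.0022) with the block. Atrophy, autophagy and FoxO target genes fell by 0.14 (0.00961), such as Gadd45g (−0.64 ± 0.21), the insulin receptor substrate Irs2 (−0.93 ± 0.33) and Txnip (−0.50 ± 0.19). In these lists 0 genes passed adjusted over the list alone or over all genes. With an estimated correlation the adjusted p was 0.706 for clock genes (0.86 in KO) and 0.737 for FoxO targets. With the block clock genes stood at −0.18 and FoxO targets at −0.09, both called; clock genes were called whichever array was left out, and FoxO targets lost the call without WT PBS 5 (−0.11, 0.143). The hour of sampling is not given in the sources used here.

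The probe sets at and near Zfp931 and the other genotype calls were weighed against chance and batch. Of 100 ways to regroup the arrays within treatment, the real one included, 2 gave at least 20 calls, under the limit of 5 in 100; the other gave 307, which points to a structure of the samples. Both are among the 18 that set all 3 arrays of low spike-in signal on one side, and 2 of 18 does not exclude chance for the count once the batch is matched. The blocked count was 5. For the 3 leading probe sets near Zfp931 the spread between these arrays is excluded as the cause by their own tests. The limma adjusted p over all probe sets was at most 0.00203 with the block and 0.00458 within the high batch, and all 3 were called whichever array was left out. Chance differences between animals are not excluded, as the labels do not say that the arrays are separate animals. For these 3 a batch that follows the spike-in level is excluded as sole cause, as they were called within the high batch. There the 6 probe sets differed by a median of −2.26, the nearest to 0 being −0.76. The other 14 kept a median ratio of 0.959 to the pooled difference. That ratio cannot exclude the batch, as the fit that picked the 14 used the same arrays. It also sets a difference under PBS against an average over treatments. DNA flanking the targeted gene is excluded for most, as 0 of 9 called genes with a position lie among the 200 protein-coding genes on either side of Prkcz (1, Thrap3, is on the same chromosome, and linked DNA stays open for it). The 206 other genes around Zfp931 had a median of 0.027, against a common shift of the whole segment. A median cannot show scattered differences in both directions. At an unadjusted p under 0.05, 11 of these genes were lower and 7 higher in KO, so differing DNA over the segment is not excluded. A narrower variant between the stock of origin and SV129 could silence or mismatch probes sharing sequence. Zfp931 lies on another chromosome than Prkcz, and the labels call the mice littermates, among which such a variant need not follow the genotype. Every KO array lay below every WT array on the leading pair, which argues against it if the arrays are separate littermates. The labels do not say that they are separate animals, so it stays open, and sequencing of that interval in both genotypes would tell.

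Matrix, fibroblast and macrophage genes stood highest in WT AngII 2. A lower share of cardiomyocytes alone would raise endothelial and fibroblast markers alike. The fibroblast median exceeded the endothelial by 1.07, with lower quartile 0.57 against upper quartile 0.41, which argues against that as the sole cause. It does not exclude it, as the array was singled out for these high genes and the limits were set after a first result. Smooth muscle stood at 0.37 and atrial markers at 0.45. A stronger fibrotic response in 1 heart, or a piece of tissue taken from a scar, may be behind it; histology of that heart would separate these.

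The absence of calls for AngII averaged over genotypes does not show an absence of response. All 100 regroupings gave at least the 0 calls of the real one, as any must, so this says nothing about chance. Calls came from 7, up to 1130, which points to a structure of the samples; 6 of these set KO PBS 2 and 3 against the 3 KO arrays of low spike-in signal. With the batch as a block the real count was 0 as well.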
